A study of Mus musculus with 23 samples.

How the data were processed

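Spinal cord tissue was taken from mice in which Cre recombinase under a mouse Gfap promoter places a hemagglutinin (HA) tag on ribosomes, a system known as RiboTag. The animals had a severe crush injury of the spinal cord (SCI) at thoracic level 10, and the hydrogel groups received a depot 2 days later. The middle 3 mm of the lesion was collected 14 days after injury. RNA precipitated through the tag (HA, meant to hold ribosome-associated RNA of astrocytes) and RNA that was not precipitated (FT, the flow-through) were sequenced separately. The study description assigns the flow-through to cells other than astrocytes, but it held astrocyte transcripts too, with Aqp4 at 346 to 603 CPM over the FT groups. The 23 libraries form 6 groups, named by fraction and by treatment: SCI only, hydrogel CT, and hydrogel with growth factors. What CT stands for is not explained by the labels. The series title names FGF and EGF as the growth factors, whereas the column names of the deposited tables call the same group BDNF and NT3 gel and the hydrogel CT group EmGel. This conflict was not settled here, so the group is called hydrogel with growth factors throughout.

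The labels' protocols describe low-input cDNA amplification with the NuGEN Ovation system, fragmentation and paired-end libraries. Per the submitters' processing notes, CASAVA 1.8.2, edgeR and the mouse genome build mm10 were used. The aligner, the counting program, its strand setting and the annotation release are not given in the sources used here. Reads of overlapping or antisense genes and of near-identical copies could therefore not be told apart. The authors deposited a table for each fraction with whole-number counts of reads per Ensembl transcript, checked here as whole numbers with unequal library totals. The HA table has 10389 rows and that of FT 5001. The smallest row total was 10 in the HA table and 11 in the FT table, so rows with fewer reads are not listed. Per the file headers, the authors also give an edgeR log2 fold change, a p-value and a false discovery rate for each pair of treatments. A further 45 columns of per-sample values, 23 of normalised counts and 22 of log ratios, were not used.

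Counts were summed over the transcripts of a gene symbol, which gave 9363 genes in HA and 4898 in FT. Rows without a symbol, 136 in HA and 35 in FT, were left out of library sizes and tests and held between 0.00272% and 0.319% of a library's counts. Transcripts were matched to GENCODE release M21 (mm10) for gene type, position and GC content, which covered 98.3% of HA rows and 99.1% of FT rows. Coordinates are those of that annotation. The chi-square per degree of freedom between libraries of a group ranged from 5.91 to 292, so no library was a copy of another. Amplification adds to this spread, so it does not show that the libraries are separate replicates, and each was counted as 1 replicate by its label. The labels do not state that each title number is a separate animal. The p-values measure the spread between these libraries.

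Genes were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test, with TMM library scaling and filterByExpr (minimum count 10). The 3 groups of a fraction shared a fit, and p-values were adjusted by Benjamini-Hochberg over the genes tested in a comparison, with a threshold of 0.05. All tests were two-sided. CPM is the count relative to the TMM-scaled library size, given as mean and SD over libraries. Because the scaling follows the typical gene, CPM does not show the share of loci that take most of a library, and these loci are given as a percent of counts. HA was compared with FT in the 10 title numbers present in both fractions, on the 4781 genes listed in both tables, with terms for treatment and fraction. A fit with the title number as a block was the alternative. The study description takes both fractions from the same tissue samples, and that a shared title number marks the same tissue was inferred from this. Correlations of their deviations from the group means ranged from 0.0086 to 0.104, and 2 of 10 were above 0.1. Of the 10 HA libraries, 8 correlated better with the FT library of their own number than with the few others of their treatment. FT libraries of other treatments were not compared. Deviations from the mean of a small group depend on each other, so this count is weak support for the pairing. The difference of the growth factor effect between fractions was tested as an interaction with limma 3.58.1 (voomLmFit) with the title number as a random effect, whose within-animal correlation was 0.0526.

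Gene lists were tested with limma's camera at a correlation of 0.01, over lists with at least 3 tested members, adjusted over the lists of a comparison. The same test with an estimated correlation was the alternative. Of the 29 lists, the text gives those that passed in a comparison, the lists on FGF and EGF signalling and on proliferation where they were tested, and some others that did not pass. Members past 0.05 were counted over all genes tested and adjusted over the list alone. The groups, tests, lists and alternatives were fixed before the data were examined, except the alternatives named as chosen after seeing the data.

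Genes were named by a fixed rule. For each comparison it took the 8 genes with the largest rise and the 8 with the largest fall among those past 0.05 whose libraries did not overlap and whose mean was at least 1 CPM, leaving out unnamed gene models. It added up to 4 members past 0.05 from each list that passed, or the 2 with the smallest p where none did. It always took Gfap, Aqp4, Fgfr3, Egfr, Spry4, Dusp6, Etv5, Mki67, Lama1 and Vim. Where fewer than 10 genes passed it added the 10 with the smallest p. Not all the genes it took are printed. A fold against a group at 0 is given as a lower bound against 3 counts over the group, which covers counting error only. Reads carry no molecular identifiers.

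The alternatives set beforehand were DESeq2 size factors, DESeq2 1.42.0, no filter, at least 5 CPM in 3 libraries, a fit of only the 2 groups compared, median centring, the estimated correlation, and each library left out in turn. Chosen after seeing the data were protein-coding genes only without Lars2, transcript rows in place of gene sums, a loess on GC content per library (span 0.5) as an offset, and FT fits without the 4 libraries under 10000 protein-coding counts. Protein-coding counts and shares leave out Lars2 throughout. The planned change of a pseudocount does not apply to counts and was not run.

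The fits were tested on simulated counts with known changes, drawn at the real libraries' sizes and with a spread per gene shared by all groups. Of simulated log2 changes of 3, the HA fits recovered 2 of 59 for growth factors against hydrogel CT, 8 of 63 for hydrogel CT against SCI only and 9 of 55 for growth factors against SCI only. The FT fits recovered 56 of 65, 55 of 59 and 47 of 53 for the same comparisons. Real FT libraries of a group correlated at 0.877 to 0.943 with SCI only, 0.241 to 0.763 with hydrogel CT and 0.237 to 0.620 with growth factors. The spread thus differed between groups, and recovery in the real FT hydrogel groups may be lower than simulated. The HA against FT fit recovered 46 of 47 and the interaction 0 of 62. The common biological coefficient of variation was 1.00 in HA and 0.63 in FT.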

Results

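The series asked how astrocytes and the rest of the tissue of a spinal cord lesion differ in gene expression after severe crush injury, with and without a hydrogel depot that carries growth factors. RNA precipitated with the tagged ribosomes (HA) and flow-through RNA of the same tissue (FT) were measured 14 days after injury. The HA groups held 4 libraries of SCI only, 3 of hydrogel CT and 3 of hydrogel with growth factors. The FT groups held 4, 4 and 5. The SCI only libraries carry title numbers from 9596 to 9935 and the hydrogel libraries numbers from 1645 to 1762, so an effect of the hydrogel and one of the cohort cannot be told apart in any comparison with SCI only.

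Most reads fell on Yam1, a noncoding locus known to collect reads of ribosomal RNA. In HA, Yam1 took 91.1% ± 2.28 of the counts with SCI only (SD, n = 4), 50.5% ± 9.25 with hydrogel CT (n = 3) and 72.5% ± 4.36 with growth factors (n = 3). In FT it took 91.3% ± 1.38 (n = 4), 44.0% ± 16.9 (n = 4) and 59.3% ± 30.2 (n = 5). Total counts per library were 18497900 to 24337000, 10591100 to 12604400 and 7940020 to 11279500 in HA. In FT they were 2241600 to 5432940 with SCI only, but 19607 to 85234 with hydrogel CT and 40432 to 145365 with growth factors. Protein-coding counts without Lars2, a protein-coding gene that also collects ribosomal RNA reads, were 200560 to 772534, 2811890 to 5744990 and 279881 to 1506780 in HA. In FT they were 26658 to 252799, 4205 to 38823 and 2227 to 115263. The protein-coding share, also without Lars2, was 2.06% ± 1.31, 33.9% ± 10.3 and 9.03% ± 5.40 in HA, and 2.73% ± 1.43, 42.9% ± 16.1 and 30.0% ± 30.3 in FT. Counts of a few reads per gene were thus common in FT of the hydrogel groups, where 876 to 4551 genes were detected per library, against 3518 to 4816 with SCI only.

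**Figure D1:**
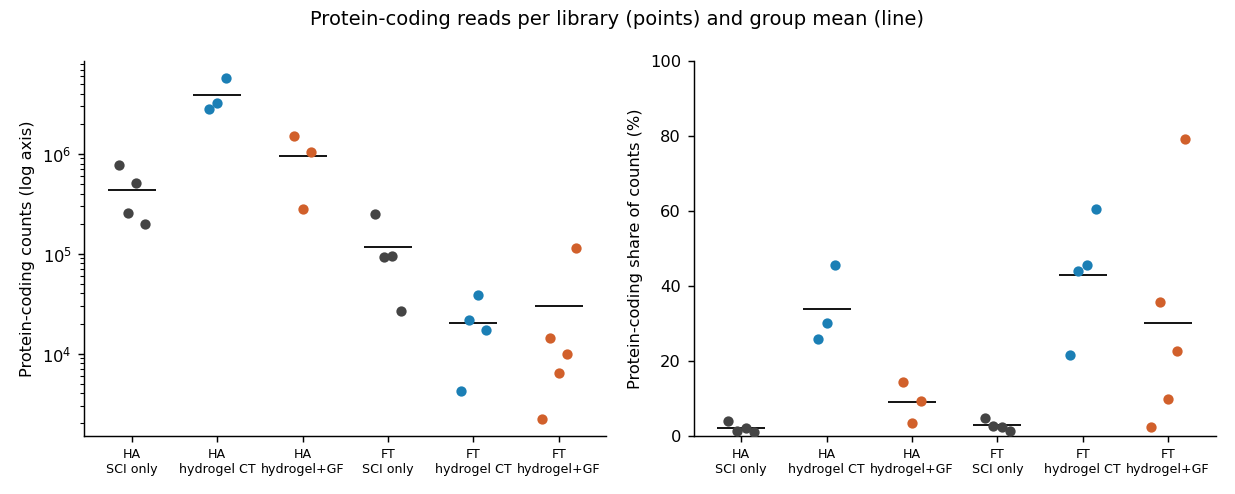
Protein-coding counts without Lars2 per library (left, log axis) and their share of all counts in percent (right) for the 6 groups, with points for libraries and lines for group means. The hydrogel CT libraries of HA hold 2811890 to 5744990 protein-coding counts and those of FT 4205 to 38823.

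The comparison of HA with FT asked which transcripts the precipitation enriched, over 10 title numbers with both fractions. Astrocyte genes were far higher in HA. Gfap, the intermediate filament of astrocytes (chromosome 11, 102887336 to 102900912), stood at 1853 ± 682 CPM in HA against 174 ± 83.3 in FT, a log2 difference of 3.47 (SE 0.39, adjusted p = 5.31e-08). Clu, a secreted chaperone, was higher by 3.91 (SE 0.38), Sox9, a glial transcription factor, by 2.67 (SE 0.44), and Aqp4, the water channel of astrocyte endfeet (chromosome 18, 15389496 to 15410982), by 1.67 (SE 0.35). The metallothioneins Mt2 and Mt1, which bind zinc, were higher by 4.62 (SE 0.45) and 4.37 (SE 0.41). Of 15 astrocyte markers tested, 13 were higher and none lower, also when adjusted over the list alone (list adjusted p = 1.31e-13, and 0.0162 with an estimated correlation).

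Genes of reactive astrocytes were also higher in HA, 5 of 5 tested and 5 adjusted over the list alone (adjusted p = 1.26e-05, and 0.0162 with an estimated correlation). They included complement C3 at 3.04 (SE 0.56) and the protease inhibitor Serpina3n at 2.85 (SE 0.47). The chemokine Cxcl10 stood at 2.28 (SE 0.68, adjusted p = 0.0144), and lost its call without number 9874 (0.0523). Vim, another intermediate filament, stood at 1.10 (SE 0.40, adjusted p = 0.0443). Its call was lost without number 1724 (0.0523), 1732 (0.0563), 1759 (0.114), 1762 (0.0544) or 9596 (0.0839). Chondroitin sulfate proteoglycans and tenascins, matrix components of the glial scar, were higher in 5 of 7 tested and 6 adjusted over the list alone (adjusted p = 9.36e-05, and 0.0126 with an estimated correlation). Brevican (Bcan) rose by 3.26 (SE 0.48), Cspg5 by 2.72 (SE 0.44) and the receptor phosphatase Ptprz1 by 1.82 (SE 0.43). Among 10 factors that support axon growth, 6 were higher and 1 lower, and 7 and 1 when adjusted over the list alone. Sdc4, a heparan sulfate proteoglycan, was higher by 2.77 (SE 0.39) and the secreted Sparcl1 by 2.47 (SE 0.38), whereas the growth factor Igf1 was lower by a log2 difference of -4.05 (SE 0.67). This list passed at adjusted p = 0.0405, but not with an estimated correlation (adjusted p = 0.0605), with the replicate block (0.0921), or without number 9596 (0.0501) or 9843 (0.0563).

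Oligodendrocyte lineage genes were enriched in the precipitate as well. Of 8 progenitor markers 7 were higher, and 8 adjusted over the list alone (adjusted p = 5.07e-07, and 0.00475 with an estimated correlation). The lineage transcription factors Olig2 and Olig1 stood at 3.40 (SE 0.48) and 3.17 (SE 0.38),, and the AMPA receptor regulator Cacng4 at 1.98. Of 6 neural progenitor genes 3 were higher, and 4 adjusted over the list alone, led by Olig2 and the transcriptional regulator Id3 at 3.05 (SE 0.50) (adjusted p = 0.0107, and 0.0241 with an estimated correlation). Of 13 oligodendrocyte markers 5 were higher, and 6 adjusted over the list alone. They included the myelin proteins Mag at 2.26 (SE 0.50) and Cldn11 at 1.43 (SE 0.40). The oligodendrocyte list passed at adjusted p = 0.0367, but not with an estimated correlation (adjusted p = 0.497) or without number 1732 (0.200).

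Transcripts of microglia, macrophages and neurons were lower in HA. Of 11 microglia and macrophage markers 10 were lower, and 11 adjusted over the list alone (adjusted p = 5.44e-14, and 0.0197 with an estimated correlation). They included the signalling adaptor Tyrobp at -3.99 (SE 0.70), lysozyme Lyz2 at -3.79 (SE 0.53) and the lysosomal protein Laptm5 at -3.65 (SE 0.61). The leukocyte tetraspanin Cd53 was the lowest named gene at -5.44 (SE 0.71), and the ferritin heavy chain Fth1 stood at -4.05 (SE 0.35, adjusted p = 2.43e-10). Of 14 neuron markers 11 were lower, and 12 adjusted over the list alone (adjusted p = 1.13e-14, and 0.000448 with an estimated correlation). The vesicular glutamate transporter Slc17a6 stood at -4.33 (SE 0.83), the synaptic protein Snap25 at -3.81 (SE 0.62) and the neurofilament Nefl at -3.49 (SE 0.42). Of 18 ribosomal protein genes 9 were lower, and 10 adjusted over the list alone (adjusted p = 1.30e-08, and 0.0228 with an estimated correlation), such as Rps24 at -2.33 (SE 0.36) and Rps4x at -2.26 (SE 0.33). Dusp6, a phosphatase induced by FGF signalling, was lower in HA at -2.28 (SE 0.77, adjusted p = 0.0312), a call lost without number 1685 (0.0601), 1687 (0.0698), 1759 (0.0512), 1762 (0.0539) or 9596 (0.0541). The proliferation gene Mki67 stood at 0.42 (SE 0.67, adjusted p = 0.712). The FGF and EGF feedback list, with 3 genes tested, did not pass (adjusted p = 0.883, 2 higher and 1 lower adjusted over the list alone).

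Of 3295 genes tested between HA and FT, 678 passed, 435 higher and 243 lower in HA. In 69 of the 678 the libraries of the fractions did not overlap. With the replicate block 673 passed, of which 600 were shared with the fit without it. Some genes belong to more than 1 list, such as Gfap to those of astrocytes and reactive astrocytes and Olig2 to those of neural and oligodendrocyte progenitors.

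**Figure D2:**
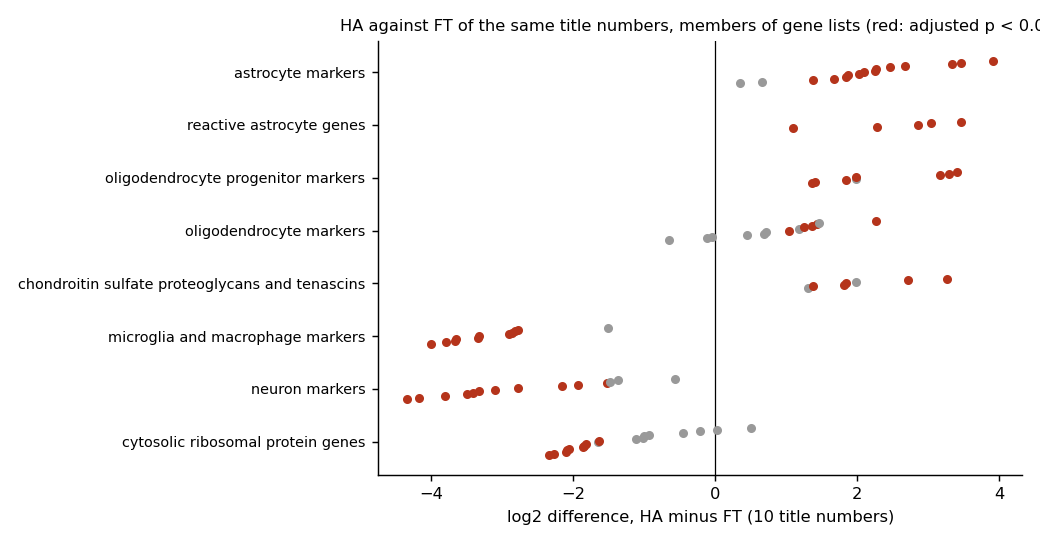
The log2 difference of HA minus FT (horizontal axis) for each tested member of 8 gene lists, over 10 title numbers, with members past an adjusted p of 0.05 in red. Astrocyte markers lie to the right of 0, with Gfap at 3.47, and microglia and neuron markers to the left.

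The comparison of HA with growth factors against HA with hydrogel CT asked what the growth factors changed in the precipitated RNA. Since oligodendrocyte lineage genes were enriched in HA as well, its differences cannot be assigned to astrocytes alone. The 6 genes that passed were all higher with growth factors under the TMM scaling, and all are loci known to collect ribosomal RNA reads: Lars2 by a log2 difference of 2.98 (SE 0.50), Yam1 by 3.05 (SE 0.52), and Gm15564, Gm23388, Gm24270 and Gm24187 by 2.96 to 3.34, each at adjusted p = 0.0397 (n = 3 and 3). These differences are relative to the typical gene. As a share of all counts Lars2 was 8.81% ± 1.74 against 6.67% ± 1.30 with hydrogel CT, with libraries that overlap, and Yam1 72.5% against 50.5%. Lars2 also encodes the mitochondrial leucyl-tRNA synthetase (chromosome 9, 123366927 to 123462666). None of the named astrocyte or growth factor response genes passed in edgeR's test. Gfap stood at 1291 ± 427 CPM against 827 ± 178, a log2 difference of 0.64 (SE 0.41, adjusted p = 0.515), and Aqp4 at -0.44 (SE 0.46, adjusted p = 0.703). Egfr, the EGF receptor, had 0 to 8 counts per library with growth factors and 152 to 675 with hydrogel CT, a log2 difference of -4.44 (SE 1.58, adjusted p = 0.267). It passed with DESeq2 alone among the alternatives (adjusted p = 0.0293, range 0.0293 to 0.444). The FGF feedback genes Spry4 at 0.96 (SE 1.60) and Dusp6 at 0.31 (SE 1.53), and Mki67 at 0.52 (SE 1.25), had errors that span large changes in either direction, and Vim stood at -0.02 (SE 0.58). Fgfr3, Etv5 and Lama1 had too few counts in HA to be tested.

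Lists of FGF and EGF feedback genes (11 tested, adjusted p = 0.648), FGF and EGF receptors and ligands (8 tested, 0.823), proliferation genes (15 tested, 0.950) and astrocyte markers (17 tested, 0.648) did not pass in this comparison. Adjusted over the list alone, 1 of the feedback genes was lower and no member of the other lists passed. Among 15 oligodendrocyte markers 12 had a positive log2 difference, such as Cldn11 at 1.62 (SE 0.60) and the iron carrier Trf at 2.60 (SE 1.08). None of the 15 passed, also adjusted over the list alone. That list passed as a group at adjusted p = 0.0102, but not with an estimated correlation (adjusted p = 0.852) or without hydrogel CT library 1762 (0.139). Of the 6654 genes tested by edgeR's quasi-likelihood test, 886 had an unadjusted p under 0.05, and the protein-coding share without Lars2 was 9.03% with growth factors against 33.9%. DESeq2 called 293, and 0 passed with DESeq2 size factors, a minimum of 5 CPM, only the 2 groups in the fit, or protein-coding genes alone. No gene passed without hydrogel CT library 1724, 1759 or 1762 or growth factor library 1687 (0 calls each, with the 6 genes at adjusted p from 0.0666 to 0.294), and 13 passed without growth factor library 1685. Without library 1687 the log2 difference of Gm24187 was 1.98 in place of 3.24.

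The comparison of HA with hydrogel CT against HA with SCI only asked what the depot changed in the precipitated RNA, with the cohort confounded. Mcl1, an inhibitor of apoptosis, rose with hydrogel CT from 13.5 ± 10.6 to 105 ± 45.1 CPM, a log2 difference of 2.96 (SE 0.58, adjusted p = 0.0425, n = 4 and 3), and Chpt1, an enzyme of phosphatidylcholine synthesis, rose by 3.97 (SE 0.77, adjusted p = 0.0402). Dlgap1, a postsynaptic scaffold protein, fell from 35.8 ± 16.5 to a mean of 0.565 CPM (log2 difference -5.97, SE 0.93, adjusted p = 0.00846). The other 9 genes that fell were loci of ribosomal RNA reads or unnamed gene models, among them Yam1 (-4.91, SE 0.56) and Lars2 (-2.76, SE 0.48). The direction of Lars2 depends on the TMM scaling, since its share of all counts was 6.67% ± 1.30 with hydrogel CT against 3.00% ± 0.727 with SCI only.

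Of 17 astrocyte markers 11 had a positive log2 difference in this comparison, and 7 rose when adjusted over the list alone. The glutamate transporter Slc1a3 stood at 4.91 (SE 1.16, adjusted p = 0.114), with 0.279 to 0.964 CPM per library of SCI only, a few reads each. Aqp4 stood at 1.59 (SE 0.43, adjusted p = 0.150), while Gfap stood at -0.33 (SE 0.39, adjusted p = 0.742) and Vim at 0.60 (SE 0.54). Of 13 microglia and macrophage markers 11 were negative and 1 fell adjusted over the list alone, with C1qa, a subunit of complement C1q, at -4.78 (SE 1.34, adjusted p = 0.171). Of 12 genes of antigen presentation and interferon responses 10 were negative and 2 fell adjusted over the list alone, with the interferon-induced Bst2 at -3.60 (SE 1.05). Of 12 oligodendrocyte progenitor markers 9 were negative and 1 fell adjusted over the list alone, with Gpr17 at -2.67 (SE 0.67). Of 12 immediate early and heat shock genes 10 were negative and 2 fell adjusted over the list alone, with the AP-1 factor Junb at -6.95 (SE 1.81), where library 9935 carried the SCI only mean (9.76 CPM against 0.193 to 1.20), and the stress factor Atf3 at 0 counts against 0 to 19 per library. No member of these 5 lists passed over all genes in edgeR's test, whereas Slc1a3, C1qa, Bst2, Gpr17 and Junb passed with DESeq2, and Slc1a3, Aqp4, Bst2 and Gpr17 in a fit of only the 2 groups. The lists passed as groups at adjusted p = 0.0369, 0.00432, 0.00432, 0.0122 and 0.0327 in that order, but none did with an estimated correlation (adjusted p = 0.702, 0.623, 0.623, 0.552 and 0.530). The astrocyte list was lost without library 9596 (0.186), 9843 (0.145), 9874 (0.0646), 1759 (0.0549) or 1762 (0.896). The microglia list was lost without 9874 (0.0646) or 1762 (0.137), the progenitor list without 1762 (0.183), and the immediate early list without 9596 (0.175), 9874 (0.0646), 9935 (0.205) or 1762 (0.137). The GC correction ended the calls of the astrocyte (0.0597), progenitor (0.329) and immediate early lists (0.453), and a minimum of 5 CPM those of the astrocyte (0.122), antigen presentation (0.0580) and immediate early lists (0.938). Egfr stood at 2.35 (SE 1.30), Spry4 at -2.69 (SE 1.59), Dusp6 at -1.20 (SE 1.47) and Mki67 at -0.14 (SE 1.17), none of them past the threshold. The lists of FGF and EGF feedback genes (adjusted p = 0.846, 2 of 11 higher adjusted over the list alone), FGF and EGF receptors and ligands (0.649, none) and proliferation genes (0.854, none) did not pass.

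In all, 13 of 6654 genes passed between HA with hydrogel CT and SCI only, 3 higher and 10 lower, against 1 and 10 with DESeq2 size factors. The GC correction kept 4 of these calls, and 2 were kept on protein-coding genes. The count was 5 without SCI only library 9843, 9874 or 9935, 3 without hydrogel CT library 1724 or 1759, and 4 without 1762. Dlgap1 was lost without 1724 (0.0861), 1759 (0.0972) or 1762 (0.0632). Mcl1 was lost without 9843 (0.175), 9874 (0.114), 9935 (0.214), 1724 (0.139), 1759 (0.158) or 1762 (0.0632). Chpt1 was lost without any 1 of the 7 libraries (0.0694 to 0.308). After the correction for GC content, chosen after seeing the data, Mcl1 stood at 2.50 (adjusted p = 0.201) and Chpt1 at 2.01 (0.587). Over all alternatives the adjusted p ranged from 0.00442 to 0.214 for Mcl1 and from 8.11e-05 to 0.587 for Chpt1.

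The comparison of HA with growth factors against HA with SCI only took the full treatment against injury alone, again with the cohort confounded. Mcl1 rose from 13.5 ± 10.6 to 513 ± 55.1 CPM (n = 4 and 3), a log2 difference of 5.24 (SE 0.63, adjusted p = 0.00107). Etfa, a subunit of the electron transfer flavoprotein of mitochondria, rose by 4.79 (SE 0.85), the chromatin remodeller Atrx by 4.18 (SE 0.89) and Dynlt3, a dynein light chain, by 3.74 (SE 0.63, adjusted p = 0.0222). Rnf141, Cldnd1 and Htatsf1 rose by 3.72 to 4.45, and Wac was at least 134-fold higher (adjusted p = 0.0411). Pkm, the pyruvate kinase of glycolysis, fell by 6.66 on the log2 scale (SE 1.39, adjusted p = 0.0411), as did Ttyh2, a chloride channel family member, at -4.86 (SE 0.85), and the synaptic adhesion protein Lrrc4b at -4.34 (SE 0.85). Natd1 stood at -5.48 (SE 1.05), Trp53rka had 0 to 2 counts per library against 18 to 382 (adjusted p = 0.0346), and Ephb1, an ephrin receptor, was at least 105-fold lower (adjusted p = 0.0381).

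Of 17 astrocyte markers 14 had a positive log2 difference between growth factors and SCI only. None passed over all genes and 6 rose adjusted over the list alone. Slc1a3 stood at 5.04 (SE 1.17, adjusted p = 0.0521) and the gap junction protein Gja1 at 1.75 (SE 0.48, adjusted p = 0.0899). Both passed with DESeq2, and Slc1a3 also under some other alternatives, with adjusted p from 0.00103 to 0.202 over all of them. Slc1a3 had 3 to 649 counts with growth factors, its libraries overlapped with SCI only, and its log2 difference was 2.77 without library 1685. The list passed at adjusted p = 0.0222, but not with an estimated correlation (adjusted p = 0.950) or without library 9596 (0.127), 9843 (0.115) or 1732 (0.0553). Gfap stood at 0.31 (SE 0.38, adjusted p = 0.680), Aqp4 at 1.15 (SE 0.43, adjusted p = 0.158) and Vim at 0.58 (SE 0.54). Egfr stood at -2.09 (SE 1.43), Spry4 at -1.73 (SE 1.56), Dusp6 at -0.89 (SE 1.48) and Mki67 at 0.38 (SE 1.17), none of them past the threshold. Nor did the lists of FGF and EGF feedback genes, of FGF and EGF receptors and ligands and of proliferation genes pass (adjusted p = 0.926 each, with no member past 0.05 adjusted over the list alone).

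In all, 29 of 6654 genes passed between HA with growth factors and SCI only, 22 higher and 7 lower. A fit of only the 2 groups kept 5 of these calls, and the GC correction kept 21. The count was 6, 5, 2 and 2 without SCI only library 9596, 9843, 9874 or 9935, and 127 and 109 without growth factor library 1687 or 1732. Mcl1 passed without any 1 of the 7 libraries (highest adjusted p = 0.0124). The other genes named as passing, Wac, Etfa, Rnf141, Atrx, Cldnd1, Dynlt3, Htatsf1, Ephb1, Trp53rka, Pkm, Natd1, Ttyh2 and Lrrc4b, were lost without 9874 (0.123 to 0.167) or 9935 (0.0965 to 0.134). Without 9596 (0.0647 to 0.118) or 9843 (0.0691 to 0.121) 10 of these 13 were lost, 6 without 1685 (0.0538 to 0.262), and Atrx without 1732 (0.120). Rnf141 rested on library 1685, with a log2 difference of 1.88 without it, and Atrx stood at 2.54 without 1732.

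Flow-through RNA with growth factors was compared with flow-through RNA with hydrogel CT to ask what the growth factors changed in the RNA that was not precipitated. No gene passed among the 610 tested by edgeR's quasi-likelihood test, 23 had an unadjusted p under 0.05, and DESeq2 called 0. Of 10 neuron markers 9 had a positive log2 difference, such as the neurofilaments Nefl at 1.14 (SE 0.65) and Nefm at 1.06 (SE 0.77). Of 11 astrocyte markers 10 were negative, such as Gjb6, a gap junction protein, at -1.36 (SE 0.87), and glutamine synthetase (Glul) at -0.87 (SE 0.64). Gfap stood at 0.88 (SE 0.71), Aqp4 at -0.40 (SE 0.78) and Vim at -0.48 (SE 0.74), each at adjusted p = 0.956. These values rest on few libraries, since Nefm stood at 0.45 without library 1687, Gjb6 at -0.67 and Glul at -0.52 without 1683, and Aqp4 at -2.17 without 1729. Adjusted over the list alone, no member of either list passed. The neuron list passed as a group at adjusted p = 0.0214 and the astrocyte list at 0.0304, but neither did with an estimated correlation (adjusted p = 0.736 and 0.766). The neuron list was lost without library 1683 (0.127), 1685 (0.0559), 1687 (0.117) or 1732 (0.0784), and the astrocyte list without 1683 (0.696), 1762 (0.0955), 1685 (0.0738) or 1732 (0.656). Of the genes always named, Dusp6 and Mki67 had too few counts for the FT comparisons, and Fgfr3, Egfr, Spry4, Etv5 and Lama1 have no row in the FT table, so their counts are not known.

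Flow-through RNA of each hydrogel group was also compared with that of SCI only, with the cohort confounded. C1qa, a complement subunit made by microglia and macrophages (chromosome 4, 136895917 to 136898803, protein-coding) fell from 1166 ± 328 CPM with SCI only to 28.9 ± 35.4 with hydrogel CT, a log2 difference of -5.81 (SE 0.97, adjusted p = 0.000663, n = 4 and 4). With growth factors it stood at 20.9 ± 15.4 (n = 5), a log2 difference of -6.35 (SE 0.94, adjusted p = 8.99e-05). Its neighbour C1qb (chromosome 4, 136880129 to 136886187), another C1q subunit, fell to 84.8 ± 67.4 from 553 ± 286 CPM with growth factors (log2 difference -2.77, SE 0.78, adjusted p = 0.0395). Lysozyme Lyz2 fell from 7347 ± 4619 to 653 ± 552 CPM with growth factors (-3.52, SE 0.96, adjusted p = 0.0393). In contrast Cx3cr1, the fractalkine receptor of microglia, rose with growth factors from 16.1 ± 20.1 to 203 ± 178 CPM (3.51, SE 0.95, adjusted p = 0.0376), with libraries that overlap.

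Of 8 microglia and macrophage markers tested in FT, 1 fell with hydrogel CT, and 4 fell and 1 rose adjusted over the list alone (list adjusted p = 0.0061, but 0.753 with an estimated correlation). With growth factors 3 fell and 1 rose, and 6 fell and 1 rose adjusted over the list alone (list adjusted p = 0.000369, but adjusted p = 0.437 with an estimated correlation). Among single genes, with hydrogel CT the log2 difference was -3.71 (SE 0.93) for the lysosomal protease Ctsd, -4.14 (SE 0.79) for the ribosomal protein Rplp1, -3.14 (SE 0.82) for the elongation factor Eef2 and -3.31 (SE 0.73) for the glutathione peroxidase Gpx1, and the ribosomal protein Rpsa fell as well (adjusted p = 0.0208). The list of cytosolic ribosomal protein genes did not pass with hydrogel CT (adjusted p = 0.353) or growth factors (0.231), with 0 of 12 members past the threshold, also adjusted over the list alone. With growth factors it was -3.29 (SE 0.87) for Ctsd, -3.01 (SE 0.70) for Npc2, a lysosomal cholesterol carrier, -3.04 (SE 0.70) for Rplp1, -3.29 (SE 0.65) for the membrane protein Itm2c, -3.17 (SE 0.65) for the G protein subunit Gnai2 and -3.07 (SE 0.77) for the small nuclear RNA Rn7sk. With hydrogel CT Yam1 stood at -5.71 (SE 1.49) and Lars2 at -3.85 (SE 1.08) under the TMM scaling, but the share of Lars2 in all counts was 4.89% ± 0.936 against 2.72% ± 0.175 with SCI only. The genes that rose with hydrogel CT were the ubiquitin-conjugating enzyme Ube2a (3.29, SE 0.89, adjusted p = 0.0395) and Gjb6 (3.27, SE 0.92, adjusted p = 0.0471). Besides Cx3cr1, the mitochondrial ADP/ATP carrier Slc25a4 rose with growth factors (3.11, SE 0.80, adjusted p = 0.0351). Gjb6 and Slc25a4 were chosen after their values were seen. Gfap stood at -1.72 (SE 0.74, adjusted p = 0.208) with hydrogel CT and -0.84 (SE 0.68, adjusted p = 0.530) with growth factors, Aqp4 at 0.78 (SE 0.82) and 0.37 (SE 0.78), and Vim at -0.99 (SE 0.72) and -1.47 (SE 0.70), none of them past the threshold.

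**Figure D3:**
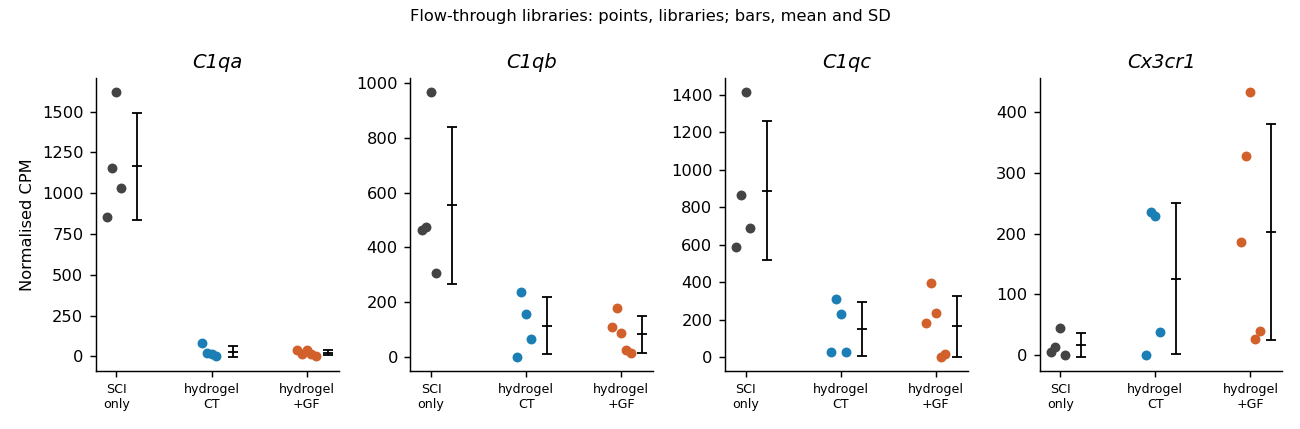
CPM of C1qa, C1qb, C1qc and Cx3cr1 in each flow-through library (points), with the mean and SD of each group (bars). C1qa falls from 1166 ± 328 CPM with SCI only to 28.9 ± 35.4 and 20.9 ± 15.4 in the hydrogel groups.

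With hydrogel CT 19 of 610 genes passed in FT, 2 higher and 17 lower, against 0 and 6 with DESeq2 size factors. With growth factors 23 passed, 2 higher and 21 lower, against 2 and 4 with DESeq2 size factors, and a fit of only the 2 groups kept 11 of these calls. C1qa and Rplp1 passed in both comparisons without any 1 library, and Itm2c and Gnai2 did so with growth factors. For hydrogel CT the count was 10, 8, 5 and 5 without SCI only library 9596, 9843, 9874 or 9935, and 6, 4 and 4 without hydrogel CT library 1724, 1759 or 1762. Ube2a (0.128 to 0.237) and Eef2 (0.0561 to 0.148) were lost without any 1 of the 8 libraries. Ctsd, Rpsa, Lars2 and Yam1 were lost without 9874 (0.0543 to 0.0949), 9935 (0.0624 to 0.107), 1724 (0.0654 to 0.108), 1759 (0.0671 to 0.146) or 1762 (0.0725 to 0.172), Ctsd and Lars2 also without 9843 (0.0702 and 0.0819), and Gpx1 without 1724 (0.0654) or 1762 (0.0725). For growth factors the count was 12, 9, 9 and 10 without SCI only library 9596, 9843, 9874 or 9935, and 12 and 11 without growth factor library 1687 or 1732. Lyz2 and Ctsd were lost without 9843 (0.105 and 0.0726), 9874 (0.0539), 1687 (0.0600) or 1732 (0.0708 and 0.0546), Npc2 without 9874 (0.0559), and Rn7sk without 9843 (0.0677), 9874 (0.0591), 9935 (0.0899) or 1732 (0.0632). Cx3cr1 was lost without 9596 (0.140), 9843 (0.127), 9935 (0.123) or 1687 (0.0914), and C1qb without any library but 1685 (0.0622 to 0.226).

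The size of these differences went with the GC content of the transcripts. Across genes, which are not independent replicates, Spearman's rho between the log2 difference and GC content was -0.496 and -0.300 in HA, and -0.497 and -0.427 in FT, for hydrogel CT and growth factors against SCI only. Between the hydrogel groups it was 0.0993 in HA and 0.139 in FT. The genes that fell in FT had a median GC content of 57.0% with hydrogel CT and 57.2% with growth factors, against 46.3% for all genes tested. With GC content corrected, an alternative chosen after seeing the data, 1 gene passed in FT with hydrogel CT and 6 with growth factors. C1qa then stood at -3.62 (SE 0.93, adjusted p = 0.137) and -4.15 (SE 0.92, adjusted p = 0.0196), and Cx3cr1 with growth factors at 4.33 (SE 1.01, adjusted p = 0.0266). Over all alternatives the adjusted p of C1qa ranged from 9.74e-09 to 0.137 with hydrogel CT and from 5.46e-10 to 0.0196 with growth factors. Rplp1 stood at -2.27 (0.236) and -0.87 (0.597), C1qb with growth factors at -0.80 (0.641), Lyz2 at -2.55 (0.189) and Ctsd at -2.23 (0.291) and -1.39 (0.452).

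**Figure D4:**
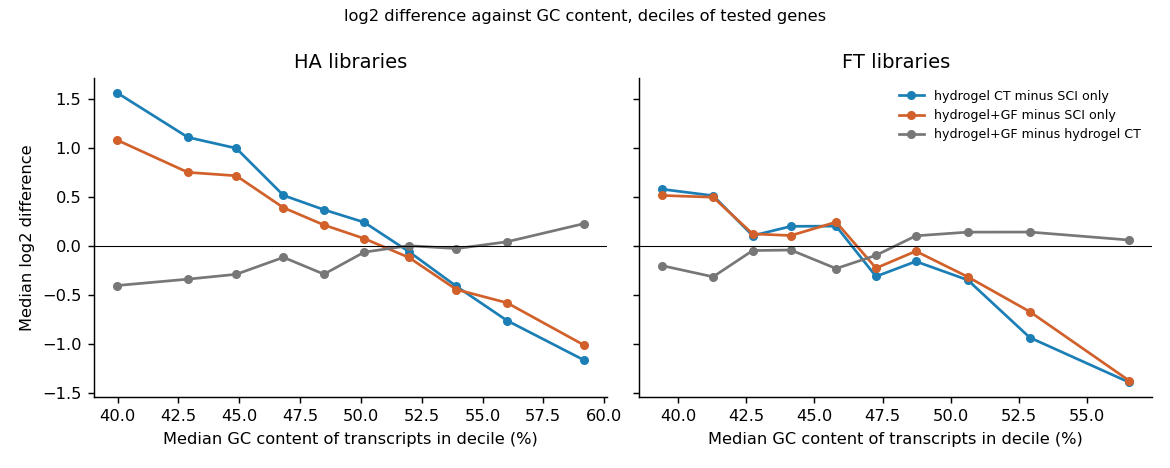
Median log2 difference between groups (vertical axis) against the median GC content in percent of 10 equal classes of tested genes, for HA (left) and FT (right), with a line for each comparison. For hydrogel CT against SCI only in HA the median falls from 1.56 in the lowest class to -1.17 in the highest.

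Whether the growth factor effect differed between fractions was tested itself, as an interaction over HA and FT libraries. None of 4675 genes passed with limma, 559 had an unadjusted p under 0.05, and the smallest adjusted p was 0.139. No other tool was run on this term, and 0 of 62 simulated log2 changes of 3 were recovered, so the test had little power.

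The authors' deposited table lists more changes than these fits, but the counts cover unlike sets. The authors' false discovery rates cover all 10389 transcript rows in HA and 5001 in FT, whereas 6654 and 610 genes were tested here after a filter. With no filter the fits here called 17 and 69 genes in HA, and 149 and 174 in FT, for hydrogel CT and growth factors against SCI only. At a false discovery rate of 0.05 the authors' deposited table for HA holds 250 transcripts higher and 162 lower with growth factors than with SCI only, and 107 higher and 43 lower with hydrogel CT. Between hydrogel CT and growth factors the authors' deposited table for HA holds 35 higher and 27 lower with hydrogel CT than with growth factors. The authors' deposited table for FT holds 17 higher and 437 lower with growth factors than with SCI only, 22 higher and 388 lower with hydrogel CT, and 0 between the hydrogel groups. The 29, 13, 6, 23 and 19 genes called in the fits reported here were also called in the authors' deposited table.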

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

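A library was singled out where it lay far from the others of its group, by the gap to the nearest of them over the range of the group. The HA groups of hydrogel CT and of growth factors, with 3 libraries each, were too small for this and were not checked. Of 127 groups of values checked this way 11 stood out, and 6.35 would by chance if values were independent and normally distributed. Many genes come from the same libraries, so that number is only a rough guide. The choice of values checked followed from the genes named, and no further tests were chosen after the result was seen in this part.

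In HA of SCI only, Slc1a3, a glutamate transporter, stood at 0.964 CPM in library 9843 against 0.279 to 0.344 in the others, a few reads per library. In the same library Etfa stood at 2.89 CPM against 0.748 to 0.918. Junb, an AP-1 transcription factor, stood at 9.76 CPM in library 9935 against 0.193 to 1.20.

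In flow-through RNA with growth factors, library 1729 held 1697 CPM of Aqp4 against 37.1 to 230, and 1105 CPM of Glul, glutamine synthetase, against 132 to 410. Both are astrocyte markers. Library 1732 held 1307 CPM of Tuba1a, an alpha tubulin, against 0 to 94.3, and library 1645 held 668 CPM of the ribosomal protein Rplp1 against 84.7 to 181. Library 1732 also held 115263 protein-coding counts against 2227 to 14461 in the others.

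In flow-through RNA with hydrogel CT, library 1683 held 1468 CPM of Glul against 591 to 678, and library 1724 held 272 CPM of Pabpc1, the poly(A)-binding protein, against 137 to 160. In flow-through RNA of SCI only, 3518 genes were detected in library 9935 against 4628 to 4816 in the others.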

How the results depend on the processing

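Tests chosen after the result was seen are the fits on protein-coding genes without Lars2, on transcript rows, with the GC correction and without the 4 FT libraries under 10000 protein-coding counts. The enrichment of astrocyte genes and the depletion of microglial and neuronal genes in HA held under all alternatives run on it, with 550 to 713 calls when each title number was left out. The GC correction, the transcript rows and the fit without the 4 shallow libraries were not run on HA against FT. The comparison was stable in count with median centring (636), DESeq2 size factors (649), DESeq2 (843), no filter (916) and protein-coding genes (559). The replicate block gave 673 calls and changed no call of a named gene or list but Gpc1 (adjusted p = 0.132) and the list of axon growth factors. Vim lost its call with median centring (adjusted p = 0.0817), DESeq2 size factors (0.0560) and on protein-coding genes (0.0594), and Dusp6 with no filter (0.0936). The transcript rows changed no count by over 1.5 times. The interaction called 0 genes also with no block and with median centring.

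Counts in HA are given in the order growth factors against hydrogel CT, hydrogel CT against SCI only, growth factors against SCI only, where the calls reported are 6, 13 and 29. DESeq2 gave 293, 248 and 715, DESeq2 size factors 0, 11 and 28, no filter 8, 17 and 69, a minimum of 5 CPM 0, 18 and 53, only the 2 groups 0, 113 and 5, protein-coding genes 0, 2 and 69, and the GC correction 3, 4 and 54. Leaving out each library gave 0 to 13, 3 to 15 and 2 to 127. In FT, where the calls reported are 0, 19 and 23, the count between the hydrogel groups was 0 under every alternative, leaving out each library included. The other counts were 57 and 79 with DESeq2, 6 and 6 with DESeq2 size factors, 149 and 174 with no filter, 143 and 132 with a minimum of 5 CPM, 209 and 18 with only the 2 groups, 26 and 19 on protein-coding genes, 1 and 6 with the GC correction, and 41 and 48 without the 4 shallow libraries. Leaving out each library gave 4 to 17 and 9 to 23. DESeq2 size factors moved the median log2 difference from -0.02, -0.01 and 0.01 to 0.14, 0.28 and 0.45 in FT, and in HA from -0.14 to 0.01 and from 0.27 to 0.05 in the comparisons with hydrogel CT. The cause was not tested, except that fewer libraries or other genes entered some fits by construction. Lists called were 21, or 8 with an estimated correlation. List calls ended in 6 cases with a minimum of 5 CPM, 3 with the GC correction, 3 on protein-coding genes, 2 with only the 2 groups, and 1 each with median centring, DESeq2 size factors, no filter, the replicate block and without the 4 shallow libraries.

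Genes whose log2 difference turned its sign had not passed the test. In HA, growth factors against hydrogel CT, Vim (-0.02) went to 0.14 with DESeq2 size factors and with DESeq2, 0.047 with a minimum of 5 CPM, 0.039 on protein-coding genes and 0.46 with the GC correction, and Aqp4 to 0.46 with the GC correction. The GC correction also took Gfap to 0.088 in HA, hydrogel CT against SCI only, Vim to 0.10 in FT, hydrogel CT against SCI only, and Gfap to 0.94 in FT, growth factors against SCI only. Without the 4 shallow libraries Gfap went to -0.53 and Vim to 0.11 in FT between the hydrogel groups, and Aqp4 to -1.11 in FT, growth factors against SCI only. Leaving out each library gave ranges across 0 in HA, growth factors against hydrogel CT, for Vim (-0.22 to 0.19), Dusp6 (-0.34 to 0.83), Spry4 (-0.84 to 1.45) and Mki67 (-0.34 to 1.09). It did so for Mki67 in HA of hydrogel CT (-0.69 to 1.00) and of growth factors (-0.42 to 1.54) against SCI only. In HA of growth factors against SCI only Egfr ranged from -3.21 to -0.94, and Spry4 stood at -3.48 without library 1687. In FT ranges across 0 were seen for Aqp4 with growth factors against SCI only, from -1.22 without library 1729 to 0.78, and for Tuba1a between the hydrogel groups, from -0.82 without library 1732 to 2.92. The cause was not tested. The interaction and the HA comparisons had the least power, with none or few of the simulated log2 changes of 3 recovered, and in FT only 610 genes could be tested.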

Other observations

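Chosen after the result was seen were the tests on loci of ribosomal RNA reads, on counts expected at this depth and on C1q subunits, and the GC correction. The splits of the samples and the GC comparison of called genes were set beforehand.

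Several lists of other cells and processes did not pass as groups between HA and FT, though some members did. Of 5 collagen and matrix genes tested 1 was higher in HA and 1 lower, and as many adjusted over the list alone (list adjusted p = 0.965). Of 4 pericyte and fibroblast markers 1 was higher and 1 lower, and 2 and 1 adjusted over the list alone (0.564). Of 6 genes of antigen presentation and interferon responses 1 was higher, and 1 adjusted over the list alone (0.965). Of 7 cholesterol synthesis genes 1 was higher, and 2 adjusted over the list alone (0.514), and of 8 glycolysis and hypoxia genes 1, and 1 adjusted over the list alone (0.555). Of 4 axon-repulsive guidance molecules 2 were higher and 1 lower, and 3 and 1 adjusted over the list alone (0.381). These came from limma's camera over 19 lists, and lists of few tested members have little power. The test looks for a shared direction, so a list whose members moved both ways can fail it.

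Other splits of the same libraries into groups of the same sizes were tested for as many calls as the real one. In HA, the real split was the only 1 of 35 with as many calls for hydrogel CT against SCI only (13 calls, highest other 0) and the only 1 of 35 for growth factors against SCI only (29, highest other 1). In FT it was the only 1 of 35 for hydrogel CT (19, highest other 0) and the only 1 of 100 drawn for growth factors (23, highest other 12). For HA against FT, 1 of 88 splits that exchange fractions within title numbers, the real one, gave as many (678, highest other 286). The other splits mix libraries of the groups compared, which widens the spread within a group, so fewer calls were likely in them beforehand. With 35 splits the smallest possible share is 1 of 35, and the shares were not adjusted over the comparisons. Chance is thus not excluded by these counts, and they say nothing on the cohort, which the design confounds with the hydrogel. For growth factors against hydrogel CT in HA the 10 splits are too few for a share under 0.05 (1 of 10 gave as many, 6 calls, highest other 0). So are the 20 splits of the interaction (highest other 3), where the real split called 0 genes and all 20 had to give as many. For growth factors against hydrogel CT in FT the real split called 0 genes, so all 100 splits had to give as many, and the count says nothing about chance. The highest of the other splits, with 80 calls, set libraries 1645, 1685, 1687, 1724 and 1759 against the rest. A split with many calls points to a structure among the libraries. Some genes of microglia and macrophages, looked up after the split was seen, went with it. In libraries 1645, 1685, 1687, 1724 and 1759, Lyz2 stood at 952 to 2547 CPM, against 26.9 to 343 in the rest. Cx3cr1 stood at 185 to 434 against 0 to 40.3, and C1qc at 185 to 394 against 0 to 30.5. The sets did not overlap for C1qb either, but did for C1qa. The FT means of the hydrogel groups mix both sets. Why the sets differ was not tested.

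The loci of ribosomal RNA reads were higher in HA with growth factors than with hydrogel CT. Of 11 such loci tested 6 passed, and the 5 that did not were also higher, with a median log2 difference of 2.81 (SD 1.15) relative to the typical gene. These loci share the same scaling, so those not called add no independent support. The shares of all counts differed less, with Yam1 at 72.5% against 50.5% and Lars2 at 8.81% against 6.67%. Yam1, Lars2, Gm23935, Gm24187 and Gm24270 together took 84.9% to 96.2% of a library's counts with growth factors. With hydrogel CT they took 53.4% to 73.2%. A larger share of reads on these loci was thus measured in these libraries as a whole, and its cause was not tested. Whether changes extend to protein-coding genes stays open. Among these 0 passed in edgeR's quasi-likelihood test when the loci were left out. Recovery was simulated only for the fit on all genes, at 2 of 59 log2 changes of 3. A response of astrocytes to the growth factors was not tested apart from this.

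The 22 protein-coding genes, Lars2 left out, called lower in FT of either hydrogel group than in SCI only had a GC content above that of the other tested protein-coding genes (median 56.9% against 46.1%, area under the curve 0.908). The GC correction moved their median log2 difference from -2.58 to -1.20 with hydrogel CT and from -2.53 to -0.90 with growth factors, at standard errors of about 0.70 and 0.68, and 1 of 22 was still called, because the differences shrank while the errors did not. The correction takes out any difference that follows GC content, so it cannot tell a loss of GC-rich fragments from a change of GC-rich genes. A loss of GC-rich fragments in these libraries is a candidate explanation that was not tested apart from this. Low depth stays open: the pooled counts of all 22 lay below a Poisson range at the SCI only level, but that range covers counting error only and the genes were picked as lower. An effect of the hydrogel stays open too, since the cohort is confounded with it.

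C1qa, C1qb and C1qc lie next to each other on chromosome 4 and encode subunits of the same protein, yet C1qa was far lower in FT of the hydrogel groups. Its share of the C1q counts was 44.1% with SCI only and 4.77% over the pooled counts of the 9 hydrogel libraries, with a range from 0 to 75% between libraries of few C1q counts, and 50.1% and 21.5% in HA. Fewer microglia and macrophages would lower the subunits alike, but C1qa lay below the mean of the others by a log2 difference of -3.49 (SE 1.15) with hydrogel CT and -3.75 (SE 1.11) with growth factors. GC content was 59.5% for C1qa against 57.4% and 57.5%, and the differences were -3.10 (SE 1.09) and -3.50 (SE 1.08) after correction. C1qa was singled out for its low values in these same libraries, at 0 to 4 counts per hydrogel library of FT. The errors also treat the subunits as independent. These differences thus exclude neither fewer microglia and macrophages nor GC content. In HA 4 of 6 hydrogel libraries had a C1qa share below the lowest of SCI only (44.8%), with a range from 0.450% to 65.4%. These were all the hydrogel CT libraries (0.450% to 24.0%) and growth factor library 1732 (10.8%), but not 1685 (46.5%) or 1687 (65.4%). HA is the precipitate, where microglia and macrophage markers were lower, so it does not measure the whole tissue. A loss of C1qa in the whole tissue, in some animals only or with hydrogel CT, thus stays open.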
